A study of Mus musculus with 16 samples.

How the data were processed

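Total RNA of 16 whole mouse embryos, 1 embryo per array, was labelled with biotin and hybridised to Affymetrix mouse expression arrays. Per the labels, every embryo was female, was collected before the cranial neural tube closed (11 to 14 somites) and was dissected away from its extraembryonic membranes. Somite numbers of single embryos were not given in the sources used here. Differences in stage within this range could thus not be separated from strain or genotype. The 4 groups of 4 embryos were wild type and homozygous Cecr2 gene trap embryos on the strains BALB/cCrl and FVB/N. Mutants are called mutant here whatever their phenotype, which the labels do not give per embryo. Both mutant lines had been backcrossed for more than 10 generations. Per the labels, BALB/cCrl mutants came from crosses of heterozygotes and FVB/N mutants from crosses of homozygotes, so in FVB/N the genotype could not be separated from the cross or the colony. Litters were not given in the sources used here. The deposited array numbers run group by group. Whether they give the order of processing was not stated, and in no contrast could such an order be separated from the groups.

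The values analysed were log2 expression values that the authors normalised across all 16 arrays together. The deposited series table and the deposited 4-group table held the same 45037 probe sets with identical values. The labels name RMA and GCRMA as processing tools, without versions and without saying which table each made. A deposited results table of the 4-group comparison held a score per probe set, a signed linear fold change of the group means, with the p-value of a test per probe set. The authors also deposited 3 tables normalised by gcRMA for 1 pair of groups each, in log2 units, with their fold changes and p-values, and these served as an alternative. For the pair of mutant groups, the deposited normalised table held no values of these arrays, and the deposited folds and p-values of that pair were not used here. Arrays carry no sequencing depth, and the number of arrays, 4 per group, limits the precision.

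Probe sets were joined to genes through the platform annotation and to positions on the mouse genome build GRCm38.p6 through Entrez identifiers. Of the 45037 probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, which left 18193 genes. The chromosome in the platform annotation matched that of the genome annotation for 31934 of the 32122 probe sets with both, or 99.4%. For tests on genes, each gene was represented by its probe set with the highest mean over the 16 arrays, with no regard to the groups.

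All 16 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group, no covariates and an empirical Bayes spread that followed the intensity. Contrasts were mutant minus wild type in each strain, BALB/cCrl minus FVB/N in each genotype, the interaction (the BALB/cCrl genotype effect minus that of FVB/N) and the mean of both genotype effects. P-values were two-sided and adjusted by Benjamini and Hochberg over the 45037 probe sets, and an adjusted p under 0.05 was called. Fold changes are given with the standard error (SE) of the fit, and group means with the standard deviation (SD). The R package data.table (version 1.17.8) and, under Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 handled the data, and figures were drawn with matplotlib 3.10.9.

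Before the data were examined, the contrasts, the threshold, the alternatives, 22 gene lists and the rule for naming genes had been fixed. The lists, written from general knowledge, were cranial neural tube closure genes, planar cell polarity, actin cytoskeleton and apical constriction, ISWI remodelling complexes, head mesenchyme and placode transcription factors, hedgehog pathway and ventral neural tube, retinoic acid pathway, folate and one-carbon metabolism, Hox genes, neural crest, and neural progenitors and early neurons. The others were paraxial mesoderm and myogenesis, surface ectoderm, endothelium, cardiac muscle, primitive erythroid cells, visceral endoderm and yolk sac, trophoblast and decidua, hypoxia response, p53 targets and apoptosis, immediate early and heat shock, and X and Y transcripts of sex. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists of a contrast, and again with a correlation estimated from the data. Members past the test were counted over all probe sets and adjusted over the list alone. An additional list of 18 uterine genes was written after the data had been seen.

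Named genes were, in each contrast, Cecr2, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap (for the interaction and the mean effect, called genes whatever their overlap), and up to 4 called members per list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen. Calls by chromosome, and within 10 and 20 Mb of Cecr2, were compared with all other genes by a two-sided Fisher's exact test, adjusted over chromosomes. Called probe sets shared by a pair of contrasts were counted in each direction against the number that independent calls would give.

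The fit was tested on simulated data with 45037 probe sets, of which 200 changed. At 4 against 4 arrays it recovered 26% of the probe sets changed 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 5 of its 160 calls were false. The simulated noise was normal and independent between probe sets, with no array set apart, unlike the real data. With 9 calls, the real BALB/cCrl contrast also faced a stricter p-value cut, so these shares need not hold there. RNA quality was checked from the 3' and 5' control probe sets of Gapdh and Actb in the pair tables, by an exact permutation test. Alternatives were the replicate number as a block, a filter on low values, no intensity trend, array quality weights, quantile normalisation, centring on the median, a fit on the 8 arrays of a pair, the gcRMA pair tables, a 1.5-fold threshold, a stricter threshold of 0.01 for chromosomes, any or the mean of a gene's probe sets, and leaving out each array in turn. Groups were also re-split in all 35 ways for each pair of groups, or in 100 random draws of the genotype labels for the interaction and the mean effect. Within groups of 4, an array was taken to stand apart from the other 3 when the ratio of its gap to the group's range exceeded Dixon's 95% value of 0.829.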

Results

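Expression was measured in 16 single mouse embryos, 4 in each of 4 groups. The groups were wild type embryos and embryos homozygous for a gene trap in Cecr2, on the inbred strains BALB/cCrl and FVB/N. Cecr2 encodes a bromodomain protein that partners ISWI chromatin remodellers, and its loss is known to cause exencephaly, an open cranial neural tube, to a degree that depends on the strain. All embryos were female and were collected before the cranial neural tube closed. Their levels of sex transcripts matched this in every group. The X-inactivation transcript Xist averaged 11.56 (log2) in BALB/cCrl wild types and 11.63 in FVB/N mutants, while the Y-linked gene Kdm5d averaged 3.47 and 3.37. Arrays of a group correlated with each other at 0.995 to 0.998. The first principal component held 39.3% of the variance and separated the strains, and the second held 9.4%. On the second, each mutant lay below every wild type of its strain, and FVB/N mutants 3 and 4 lay farthest out, at -24.0 and -24.7. The 3' over 5' signal of Gapdh, a sign of RNA quality, was 0.039 higher (log2) in BALB/cCrl mutants than in wild types (exact permutation p = 0.029, the smallest that 4 against 4 allows) and 0.052 higher in FVB/N mutants (exact permutation p = 0.057). For Actb these differences were -0.071 (exact permutation p = 0.20) and 0.029 (exact permutation p = 0.51). The number of arrays per group limits the precision of every value.

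**Figure D1:**
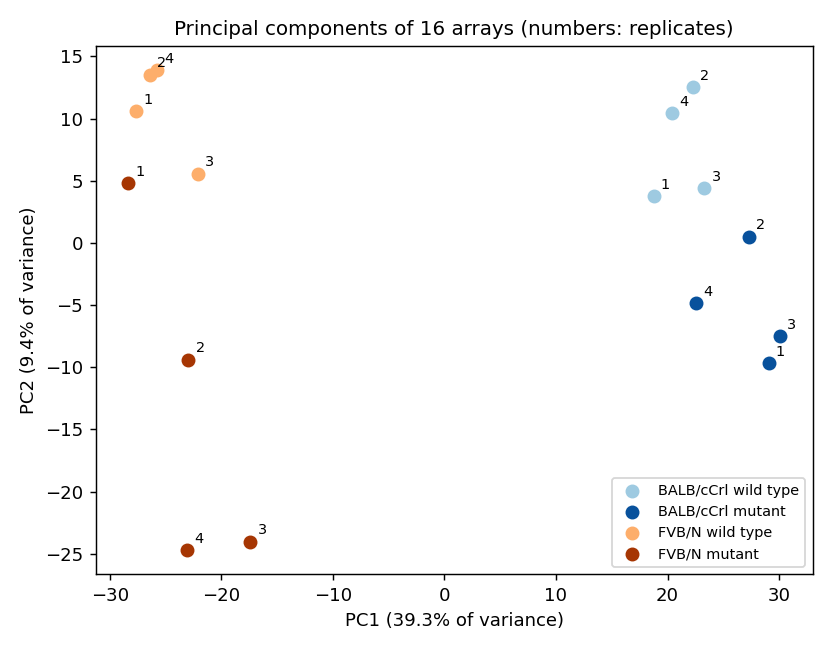
Each point is 1 array, placed by its scores on the first (39.3% of the variance) and second (9.4%) principal components of all probe sets, coloured by group and numbered by replicate. The strains part along the first axis, and FVB/N mutants 3 and 4 lie lowest on the second.

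The first comparison asked what the gene trap changed in BALB/cCrl embryos. Cecr2 itself fell most. One of its probe sets was 5.15-fold lower in mutants (log2 fold change -2.36, SE 0.107, n = 4 per group) and the other 5.23-fold lower (-2.39, SE 0.246). Of the other genes, Ncapd2, a subunit of condensin I, rose 2.05-fold (log2 fold change 1.04, SE 0.072) and Cdca3, a cell cycle gene, rose 1.45-fold (0.53, SE 0.052). Alx1, a homeobox factor of the head mesenchyme, fell 1.78-fold from 7.60 ± 0.13 to 6.77 ± 0.16 (mean log2 level and SD, n = 4). Csn3, which encodes kappa-casein, fell 2.14-fold from 7.81 ± 0.04 to 6.72 ± 0.20, and the zinc finger gene Zfp9 fell 2.52-fold from 8.39 ± 0.19 to 7.05 ± 0.34. Pianp fell 1.59-fold (log2 fold change -0.66) and the homeobox gene Zfhx4 fell 1.33-fold (-0.42).

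In all, limma called 9 of 45037 probe sets, 2 higher and 7 lower in BALB/cCrl mutants, and 4296 had an unadjusted p under 0.05. The adjusted p was 1.9e-10 and 6.8e-05 for the probe sets of Cecr2, 2.0e-07 for Ncapd2, 1.4e-05 for Csn3, 3.0e-05 for Cdca3, 2.3e-04 for Zfp9, 3.8e-04 for Pianp, 6.1e-04 for Alx1 and 0.050 (just under the threshold) for Zfhx4. Cecr2 spans 120666314 to 120771191 on chromosome 6 of GRCm38.p6, and Ncapd2, Cdca3, Zfp9 and Pianp lie within 4.5 Mb of it, while Alx1 (chromosome 10), Csn3 (chromosome 5) and Zfhx4 (chromosome 3) do not share its chromosome. Other probe sets of these genes did not all follow. The second probe set of Alx1 gave -0.42 without passing, and that of Csn3 gave -0.07. Those of Ncapd2 (0.28), Cdca3 (0.06 and 0.01), Pianp (-0.01) and Zfhx4 (-0.26) did not pass either. Alx1 and Csn3 each had a BALB/cCrl wild type 1 value apart from the other 3, at 7.80 against 7.51 to 7.56 for Alx1. The count and its direction depended on the processing and on single arrays. It was 50 with array weights and 14 with each array centred on its median (26% and 14.3% higher in mutants, against 22.2% of the 9). It was 18 without BALB/cCrl mutant 2 (44.4% higher) and 115 without BALB/cCrl mutant 4, most of them higher (77.4%). Without BALB/cCrl wild type 1 and mutant 4, a pair of arrays that stand apart from the other 6 and were left out only after the data had been seen, it was 22 (59.1% higher). The call of Zfhx4 was lost without BALB/cCrl mutant 2 (adjusted p = 0.064), mutant 3 (0.20) or wild types 1 to 4 (0.099, 0.084, 0.095 and 0.23), and with the replicate number as a block (0.0925). In the authors' gcRMA table of this pair 3 probe sets passed in a fit like the one here, and Alx1 (log2 fold change -1.22) and Csn3 (-1.59) were not among those with an adjusted p under 0.05.

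**Figure D2:**
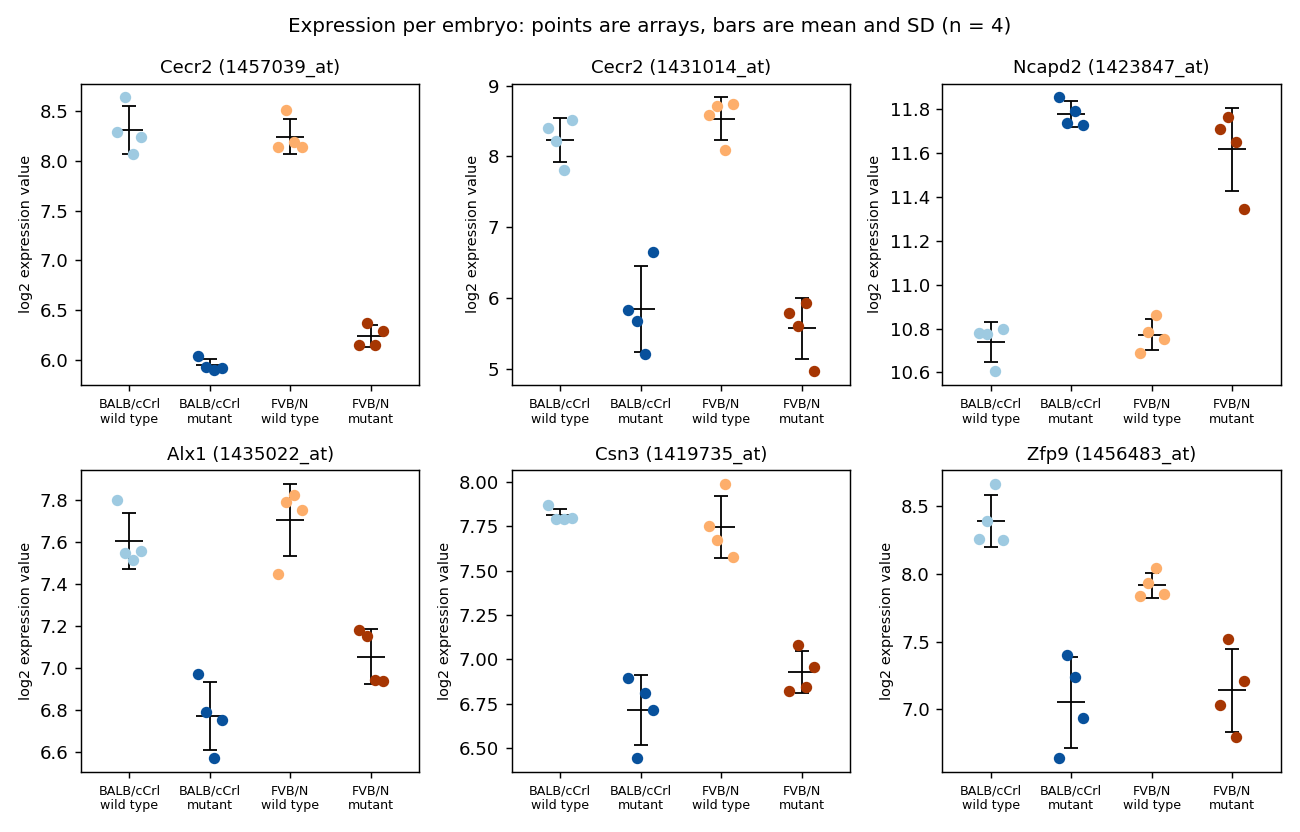
Log2 expression values of 6 probe sets called in both strains, with 1 point per array and bars for the mean and SD of 4 arrays. Both Cecr2 probe sets, Alx1, Csn3 and Zfp9 are lower in the mutants of each strain and Ncapd2 is higher, from 10.74 to 11.78 in BALB/cCrl and from 10.77 to 11.62 in FVB/N.

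Among the lists fixed beforehand, head mesenchyme and placode transcription factors were among the 5 called by camera in BALB/cCrl mutants. Of 23 measured members 18 lay below 0, with a median log2 fold change of -0.10 (camera adjusted p = 0.0016, and adjusted p = 0.34 with an estimated correlation). Alx1 alone passed over all probe sets, and 5 members fell when adjusted over the list alone. Hypoxia response genes lay higher in 21 of 23 cases with a median of 0.10 (adjusted p = 1.1e-05, and 0.34 as the adjusted p with an estimated correlation), although 0 passed in limma over all probe sets and 1 adjusted over the list alone. Targets of p53 and apoptosis genes lay lower in 19 of 22 cases (median -0.08, adjusted p = 0.0065, and adjusted p = 0.34 with an estimated correlation), with 1 member passing adjusted over the list alone. Surface ectoderm genes lay lower in 11 of 19 cases (median -0.08, adjusted p = 0.0065, 4 members adjusted over the list alone) and endothelial genes in 18 of 22 (median -0.08, adjusted p = 0.023, 1 member adjusted over the list alone). These 2 lists had an adjusted p of 0.36 and 0.87 with an estimated correlation. The other 17 lists had a camera adjusted p of 0.11 or more. Among them were the ISWI remodelling complexes, with 0 of 13 members past the test over all probe sets and 2 higher adjusted over the list alone (adjusted p = 0.11), and cranial neural tube closure genes, with Alx1 as the 1 called member of 48 and 2 lower adjusted over the list alone (adjusted p = 0.68). Without BALB/cCrl mutant 2 the head mesenchyme and p53 lists gave an adjusted p of 0.065 each and the endothelial list 0.49, which was 0.064 without wild type 2 and 0.34 without wild type 4.

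In FVB/N the question was the same, and more genes passed. Cecr2 was 4.01-fold lower by one probe set (from 8.24 ± 0.18 to 6.24 ± 0.11, mean log2 level and SD, n = 4) and 7.77-fold lower by the other (log2 fold change -2.96, SE 0.246). Cdk5rap1, which encodes an enzyme that modifies mitochondrial transfer RNA, fell at least 10.7-fold, from 7.81 ± 0.07 to 4.39 ± 0.22 (mean log2 level and SD, n = 4). That is a bound, since the mutant values of 4.06 to 4.56 lay at the level of the 10 Y-linked probe sets (3.03 to 4.88), whose genes female embryos lack, a comparison chosen after the data had been seen. Ldhb, a subunit of lactate dehydrogenase, fell 2.75-fold from 10.50 ± 0.11 to 9.05 ± 0.20, and its other 3 probe sets gave -1.14, -1.13 and -1.36. The largest rises were those of H2aj, a histone variant (3.15-fold, log2 fold change 1.66, SE 0.129), Clec1b, a lectin receptor of platelets (2.82-fold, SE 0.096 on the log2 scale), the ubiquitin ligase adaptor Klhl42 (2.13-fold) and Fgfr1op2 (2.01-fold). The rises of H2aj and Fgfr1op2 stood in 1 probe set each, since the others gave -0.05 and -0.54 for H2aj and -0.06 and 0.29 for Fgfr1op2, all without passing. Alx1 fell 1.57-fold (log2 fold change -0.65, SE 0.102), Csn3 fell by 0.82 and Zfp9 by 0.77 on the log2 scale, and Ncapd2 rose 1.80-fold (0.84, SE 0.072).

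Further falls in FVB/N mutants were those of 3110021A11Rik (2.11-fold), Zfand4 (2.07-fold), Prdm8, a member of a histone methyltransferase family (1.96-fold), Emp1 (1.85-fold, with 0.20 by its other probe set) and Kctd12b (1.80-fold, with -0.22 by its other). The helicase gene Recql rose 1.71-fold (0.40, 0.45, -0.47 and -0.08 by its other probe sets, the first 2 of them called) and Hdhd5, next to Cecr2, rose 1.61-fold (0.13 by its other). Of the named genes that rose most, all 10 lie on chromosome 6. Cdk5rap1 lies on chromosome 2, and of the 159 other genes within 5 Mb of it, a neighbourhood chosen after its values were seen, 0 were called by limma and 10 had an unadjusted p under 0.05. Within 10 Mb 2 of 241 and within 20 Mb 2 of 384 were called, Xrn2 and Foxa2 in both (Fisher's exact test, p = 1 and 0.45).

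Altogether limma called 268 probe sets in FVB/N, 79 higher in mutants and the rest lower (29.5% higher), for 199 genes, and 87 of them changed at least 1.5-fold. The adjusted p was 2.0e-09 and 1.2e-06 for Cecr2, 4.5e-14 for Cdk5rap1, 7.8e-09 for Ldhb, 2.7e-08 for Clec1b, 5.4e-07 for H2aj, 1.3e-06 for Ncapd2 and 0.0050 for Alx1. The count depended on single arrays. It was 55 without FVB/N wild type 2, 74 without wild type 3, 72 without wild type 4, 152 without mutant 3 and 101 without mutant 4, and 42 without mutants 3 and 4, a pair left out only after the data had been seen. It was 162 without the intensity trend, 169 after quantile normalisation and 13 in the gcRMA table of this pair, in which Cdk5rap1, Ldhb and Cecr2 were still called and Alx1 (-0.93), Clec1b (2.63) and Ncapd2 (0.99) were not. Without mutants 3 and 4 the call of Alx1 was lost as well (log2 fold change -0.54, adjusted p = 0.14). These mutants lay farthest from the wild types on the second principal component. Fewer calls without them were therefore likely beforehand. The share of higher calls moved as well. It was 47.4% of the 325 called in a fit on the 8 arrays of this pair, 53.8% of the 13 in the gcRMA table, 42.6% without mutant 4 and 42.9% without mutants 3 and 4. FVB/N mutants and wild types came from separate crosses, so that litter and colony went with the genotype.

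Of the gene groups, the hedgehog pathway and ventral neural tube list had the smallest camera p in FVB/N mutants, with 18 of 19 members below 0 and a median log2 fold change of -0.15 (camera adjusted p = 3.0e-06, and adjusted p = 0.33 with an estimated correlation). By their representing probe sets 1 member fell over all probe sets and 5 fell adjusted over the list alone. Foxa2, a factor of the floor plate, fell 1.48-fold (adjusted p = 0.012). That call was lost without FVB/N wild type 3 (adjusted p = 0.056) or wild type 4 (0.050). Head mesenchyme and placode factors lay lower in 20 of 23 cases (median -0.10, adjusted p = 3.0e-05, and 0.20 as the adjusted p with an estimated correlation), with Alx1 called over all probe sets and 8 lower adjusted over the list alone. By another of its probe sets the mesenchymal homeobox gene Prrx1 fell 1.58-fold (adjusted p = 0.016), a call lost without FVB/N wild type 2 (0.080), wild type 3 (0.067) or mutant 4 (0.050). Endothelial genes lay lower in 19 of 22 cases (median -0.10, adjusted p = 3.1e-04, 0 past the test over all probe sets, 5 lower adjusted over the list alone), with an adjusted p of 0.40 with an estimated correlation. Cranial neural tube closure genes lay lower in 36 of 48 cases (median -0.07, adjusted p = 5.1e-04, 2 called over all probe sets and 3 lower adjusted over the list alone), with an adjusted p of 0.33 with an estimated correlation. Cardiac muscle genes lay higher in 17 of 19 cases (median 0.18, adjusted p = 3.1e-04, 0 called over all probe sets and 2 higher adjusted over the list alone), with an adjusted p of 0.41 with an estimated correlation. Without FVB/N mutants 3 and 4, left out only after the data had been seen, the endothelial list (0.061) and the closure list (0.345) lost their calls.

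The other called lists of FVB/N had no member past the test in limma over all probe sets by the representing probe sets. Visceral endoderm and yolk sac genes lay lower in 21 of 23 cases (median -0.38, adjusted p = 0.010) and primitive erythroid genes in 15 of 16 (median -0.20, adjusted p = 0.0073), and these had an adjusted p of 0.53 and 0.52 with an estimated correlation. Genes of p53 and apoptosis lay lower in 17 of 22 cases (adjusted p = 0.0073), immediate early and heat shock genes in 16 of 23 (adjusted p = 0.040), folate and one-carbon genes in 20 of 26 (adjusted p = 0.041) and surface ectoderm genes in 13 of 19 (adjusted p = 0.041). These 4 had an adjusted p of 0.33, 0.33, 0.41 and 0.41 with an estimated correlation. Without FVB/N mutants 3 and 4 all 6 lost their calls, with an adjusted p of 0.674 for the visceral endoderm list, 0.399 each for the erythroid and p53 lists, 0.109 for the immediate early list, 0.156 for the folate list and 0.0797 for the surface ectoderm list. Several calls rested on single arrays. The visceral endoderm list had an adjusted p of 0.13 without FVB/N wild type 1, of 0.076 without wild type 4 and of 0.59, with its direction reversed, without mutant 3. The erythroid list gave 0.70 without wild type 3 and 0.24 without mutant 3, the cardiac list 0.076 without wild type 4, and the closure list 0.068 without mutant 4. The immediate early list gave 0.14 without wild type 2, 0.059 without mutant 1 and 0.18 without mutant 4. The folate list gave 0.17 without wild type 1, 0.055 without wild type 2, 0.057 without mutant 2 and 0.090 without mutant 3, and the surface ectoderm list 0.12 without wild type 1, 0.070 without wild type 2, 0.070 without mutant 1 and 0.23 without mutant 3. After quantile normalisation the p53, folate and surface ectoderm lists no longer passed (0.052, 0.11 and 0.053). With the mean of a gene's probe sets the folate and surface ectoderm lists did not pass (0.0644 each), nor did the surface ectoderm list with each array centred on its median (0.0505). The hypoxia list, with an adjusted p of 0.13, was among the 11 lists not called in FVB/N.

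A congenic line keeps DNA of the allele's donor beside the selected allele, so the next question was where the called genes lie. In FVB/N 30 of 992 genes of chromosome 6 were called (3.02%) against 61 of 17038 on other chromosomes (0.358%), an odds ratio of 8.68 with 95% limits of 5.38 to 13.7 (Fisher's exact test, adjusted p = 8.5e-15). Leaving out Cecr2, 14 of 233 genes within 10 Mb of it were called, and 19 of 311 within 20 Mb (6.11%). In BALB/cCrl 5 of 992 genes of chromosome 6 were called against 3 of 17038 elsewhere, an odds ratio of 28.8 with limits of 5.58 to 185 (Fisher's exact test, adjusted p = 4.9e-04), and all 5 lay within 4.5 Mb of Cecr2 or were Cecr2. Counting any probe set of a gene, 41 of the 47 called chromosome 6 genes in FVB/N lay within 30 Mb of Cecr2, among them Hdhd5 at 0.2 Mb, Clec1b at 8.7 Mb, H2aj at 16.1 Mb, Ldhb at 21.8 Mb and Klhl42 at 26.4 Mb. When each array was left out in turn, the odds ratio in FVB/N ranged from 4.79 without mutant 1 to 24.7 without wild type 2, and that in BALB/cCrl from 4.54 without mutant 4 to 43.2 without mutant 3.

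**Figure D3:**
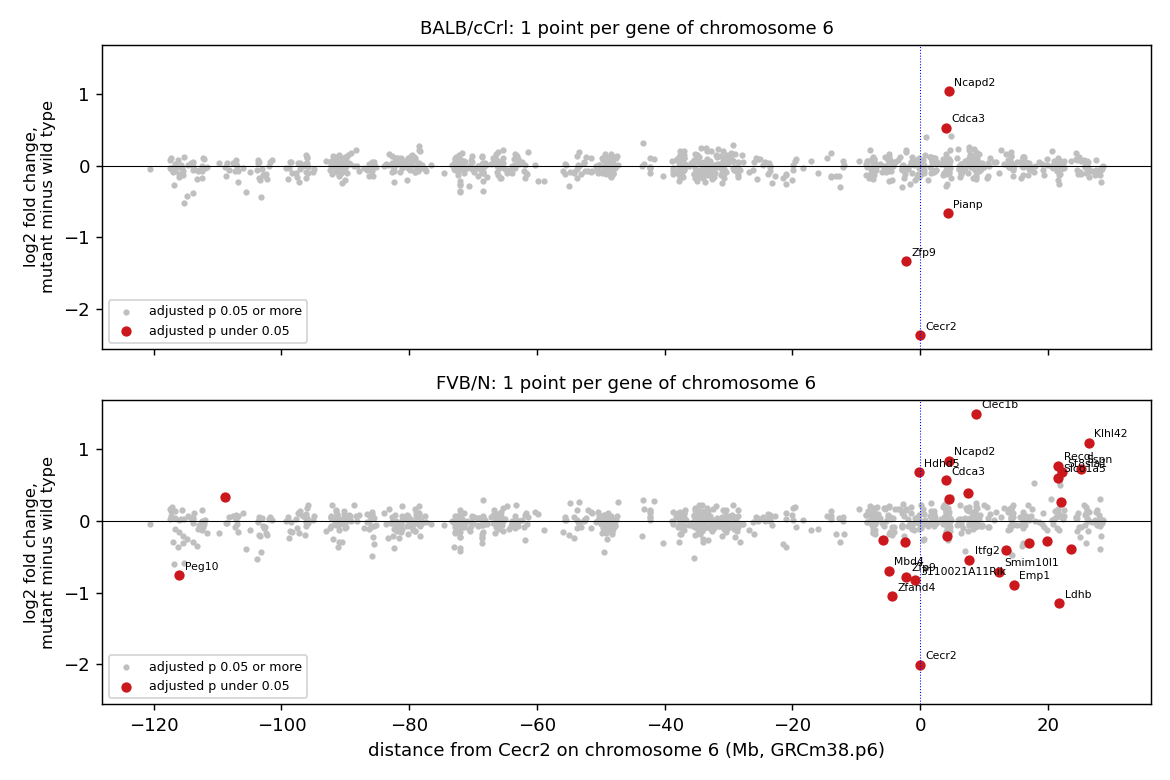
Log2 fold change of mutant minus wild type for each gene of chromosome 6 against its distance from Cecr2 in Mb (GRCm38.p6), in BALB/cCrl above and FVB/N below, with called genes in red. In FVB/N called genes crowd within 30 Mb of Cecr2, and in BALB/cCrl those called lie within 4.5 Mb.

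The interaction asked whether the difference between mutants and wild types was unlike in the strains. Cdk5rap1 showed the largest difference, with a fold change in BALB/cCrl that was at least 3.38 higher (log2) than in FVB/N, where its mutant level lay near background, and its level was 8.06 ± 0.14 in BALB/cCrl wild types and 8.02 ± 0.10 in mutants (mean and SD, n = 4). Ldhb followed with 1.54 (SE 0.122) and 3110021A11Rik with 1.27. In the other direction stood H2aj (-1.91, SE 0.183), Clec1b (-1.66, SE 0.136), Klhl42 (-1.25), Fgfr1op2 (-1.05) and Recql (-0.98), by probe sets that rose in FVB/N. Other probe sets did not follow for H2aj (-0.07 and 0.49) and Fgfr1op2 (0.04 and 0.01), and for Recql they gave -0.50 (called), -0.44, 0.44 and -0.16. For the genes called in both strains the interaction was not called, with an adjusted p of 0.74 and 0.56 for Cecr2, 0.68 for Ncapd2, 0.66 for Csn3 and 0.81 for Alx1, and Pianp, called in BALB/cCrl only, had 0.23.

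In limma 34 probe sets passed the interaction, 25 higher and 9 lower (73.5% higher, and 60.7% of the 28 called after quantile normalisation). The adjusted p was 3.9e-11 for Cdk5rap1, 2.0e-06 for Ldhb, 2.6e-06 for Clec1b and 2.1e-05 for H2aj and Recql alike. By the representing probe set of each gene, 10 of the genes called lay on chromosome 6 and 2 elsewhere (Fisher's exact test, adjusted p = 2.9e-10), and by any probe set 16 of 26 lay on chromosome 6. The count was 15 without FVB/N wild type 2, 17 without wild type 3, 16 without wild type 4, and 20 without FVB/N mutant 1 or mutant 4. It was 14 without BALB/cCrl mutant 1, 17 without mutant 3, 15 without wild type 1, 1.4e+02 without wild type 3 and 16 without wild type 4. It was 89 with the replicate number as a block, 69 with array weights and 20 without the intensity trend. Klhl42 lost its call without any 1 of several arrays, with an adjusted p of 0.076 without FVB/N wild type 2 and 0.061 without wild type 4, 0.070 and 0.062 without mutants 1 and 3, 0.088 and 0.079 without BALB/cCrl mutants 1 and 3, and 0.081, 0.065 and 0.053 without BALB/cCrl wild types 1, 2 and 4.

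Among the lists, 7 passed the interaction, each with 0 members past the test in limma over all probe sets. The hypoxia list lay higher in BALB/cCrl for 22 of 23 members (median 0.12, camera adjusted p = 3.9e-06, and adjusted p = 0.27 with an estimated correlation) with 1 member adjusted over the list alone, and the hedgehog list for 18 of 19 (median 0.15, adjusted p = 1.7e-05, likewise 0.27 as the adjusted p with an estimated correlation) with 1 member adjusted over the list alone. The cardiac list lay lower for 17 of 19 (median -0.26, adjusted p = 1.9e-05, and adjusted p = 0.58 with an estimated correlation). Weaker by the test were primitive erythroid genes (15 of 16 higher, median 0.20, adjusted p = 0.026), the ISWI remodelling complexes (10 of 13 higher, adjusted p = 0.026), neural crest genes (12 of 19 higher, adjusted p = 0.035) and closure genes (29 of 48 higher, adjusted p = 0.046). These 4 had an adjusted p of 0.81, 0.27, 0.27 and 0.69 with an estimated correlation. The number of called lists was 4 without BALB/cCrl mutant 2 and 3 without BALB/cCrl wild type 1. The ISWI list had an adjusted p of 0.067 without FVB/N wild type 4, 0.070 without BALB/cCrl wild type 1, and 0.069 and 0.073 without BALB/cCrl mutants 2 and 3. The erythroid list gave 0.66 without FVB/N wild type 3, 0.30 without FVB/N mutant 3, 0.10 and 0.088 without BALB/cCrl mutants 2 and 3, and 0.051 and 0.20 without BALB/cCrl wild types 1 and 4. The neural crest list gave 0.060 and 0.055 without FVB/N wild types 1 and 3, 0.12 and 0.079 without FVB/N mutants 2 and 4, 0.078 without BALB/cCrl mutant 1 and 0.074 without BALB/cCrl wild type 1. The closure list lost its call without any 1 of 9 arrays, with the highest adjusted p of 0.68 without FVB/N mutant 4. Without FVB/N mutants 3 and 4, the closure list had an adjusted p of 0.882, the ISWI and neural crest lists 0.147 each and the erythroid list 0.521. Quantile normalisation ended the calls of the closure and neural crest lists (0.078 and 0.0696), and the mean of a gene's probe sets those of the closure and erythroid lists (0.0871 and 0.0547). Without BALB/cCrl wild type 1 and mutant 4 the neural crest and erythroid lists lost their calls (0.0798 and 0.0609).

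The mean of both genotype effects asked what the trap changed across the strains. Besides Cecr2 (4.54-fold and 6.37-fold lower by its probe sets), Ncapd2 rose 1.92-fold (log2 fold change 0.94, SE 0.051) and Cdca3 rose 1.46-fold (0.55, SE 0.036). Zfp9 fell 2.08-fold, Csn3 fell 1.94-fold (-0.96, SE 0.070) and Alx1 fell 1.67-fold (-0.74, SE 0.072). Mnx1, a homeobox factor of motor neurons, fell 1.64-fold, and Dlx5, a homeobox factor of placodes and branchial arches on chromosome 6, fell 1.26-fold (-0.34, SE 0.051). The X-linked genes Pof1b and Gm715 fell 1.57-fold and 1.58-fold. Airn, the RNA transcribed across the imprinted Igf2r locus, rose 1.42-fold, and Mab21l2, a gene of the developing eye and midbrain, rose 1.32-fold.

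By this contrast limma called 205 probe sets, 68 higher and the rest lower (33.2% higher), of which 18 changed at least 1.5-fold. The adjusted p was 1.3e-12 and 3.3e-08 for Cecr2, 1.5e-09 for Ncapd2, 3.6e-08 for Cdca3, 1.9e-07 for Csn3, 1.6e-05 for Alx1, 0.0041 for Dlx5 and 0.0043 for Mnx1. Cdk5rap1 and Ldhb (-0.69) passed too, with a called interaction each. The count was 133 without FVB/N wild type 1, 102 without wild type 2 and 115 without wild type 4, and 330 without FVB/N mutant 1 and 133 without mutant 3. It was 131 without BALB/cCrl mutant 1, 98 without mutant 3 and 759 without mutant 4, where the direction turned and 65.5% were higher, and 131 without BALB/cCrl wild type 1 and 107 without wild type 4. With array weights it was 436. Without BALB/cCrl wild type 1 and mutant 4 it was 445, of which 65.6% were higher, and without FVB/N mutants 3 and 4 it was 70, both chosen after the data had been seen.

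Probe sets called in each strain overlapped beyond the number that independent calls would give. In the same direction 8 were shared, 2 higher against an expected 0.0035 and 6 lower against an expected 0.029, and 0 were called in opposite directions by limma, which gave 4296 and 5456 probe sets with an unadjusted p under 0.05. The shared ones were both probe sets of Cecr2, those of Ncapd2, Cdca3 and Zfp9, within 4.5 Mb of it, and those of Alx1, Csn3 and Zfhx4 on other chromosomes. The design itself makes Cecr2 shared, and its neighbours can be shared through DNA kept beside the allele. Both shared calls that were higher, Ncapd2 and Cdca3, are such neighbours. The excess beyond linked genes thus rests on Alx1, Csn3 and Zfhx4. Of all 268 probe sets called in FVB/N, 140 (52.2%) had the same sign in BALB/cCrl.

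Across both strains the head mesenchyme and placode list had the smallest camera p of the 22 lists. It lay lower in 19 of 23 cases (median -0.08, camera adjusted p = 9.0e-06, and adjusted p = 0.12 with an estimated correlation). Of its members 4 fell over all probe sets, and 1 rose and 10 fell adjusted over the list alone. Its called members were Alx1, Dlx5, Prrx1 (1.37-fold lower, adjusted p = 0.013) and Eya1, a placode factor (1.28-fold lower, adjusted p = 0.023). The call of Eya1 was lost without FVB/N wild type 1 (0.057), BALB/cCrl mutant 3 (0.061) or BALB/cCrl wild type 4 (0.065). Endothelial genes lay lower in 20 of 22 cases (median -0.08, adjusted p = 1.8e-04, 1 called over all probe sets and 7 lower adjusted over the list alone) and p53 targets in 21 of 22 (median -0.07, adjusted p = 4.0e-04, 1 called and 2 lower adjusted over the list alone). These had an adjusted p of 0.44 and 0.27 with an estimated correlation. Surface ectoderm genes lay lower in 15 of 19 cases (adjusted p = 0.0024, 2 called and 5 lower adjusted over the list alone), hedgehog genes in 15 of 19 (adjusted p = 0.0043, 1 called), closure genes in 36 of 48 (adjusted p = 0.011, 2 called and 4 lower adjusted over the list alone), folate genes in 19 of 26 (adjusted p = 0.033, 4 lower adjusted over the list alone) and Hox genes in 20 of 24 (adjusted p = 0.047). These 5 had an adjusted p of 0.44 or, for Hox genes, 0.62 with an estimated correlation. The Hox list lost its call without FVB/N wild type 1 (0.070), wild type 2 (0.061), wild type 4 (0.16) or FVB/N mutant 4 (0.43), and without BALB/cCrl mutants 1, 2 or 4 (0.056, 0.051 and 0.12) or BALB/cCrl wild type 2 (0.12), and with the replicate number as a block (0.0517). The folate list lost it without FVB/N wild type 1 (0.070), BALB/cCrl mutant 1 (0.055), mutant 3 (0.058) or wild type 1 (0.060), and the closure list without FVB/N mutant 4 (0.13). Quantile normalisation ended the calls of the Hox, folate and closure lists (0.092, 0.092 and 0.12), and so did leaving out FVB/N mutants 3 and 4 (0.34, 0.0563 and 0.324). The mean of a gene's probe sets ended those of the closure and Hox lists (0.204 and 0.0535), and centring each array on its median that of the Hox list (0.105). Without BALB/cCrl wild type 1 and mutant 4 the Hox and folate lists lost their calls (0.0903 and 0.0707).

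**Figure D4:**
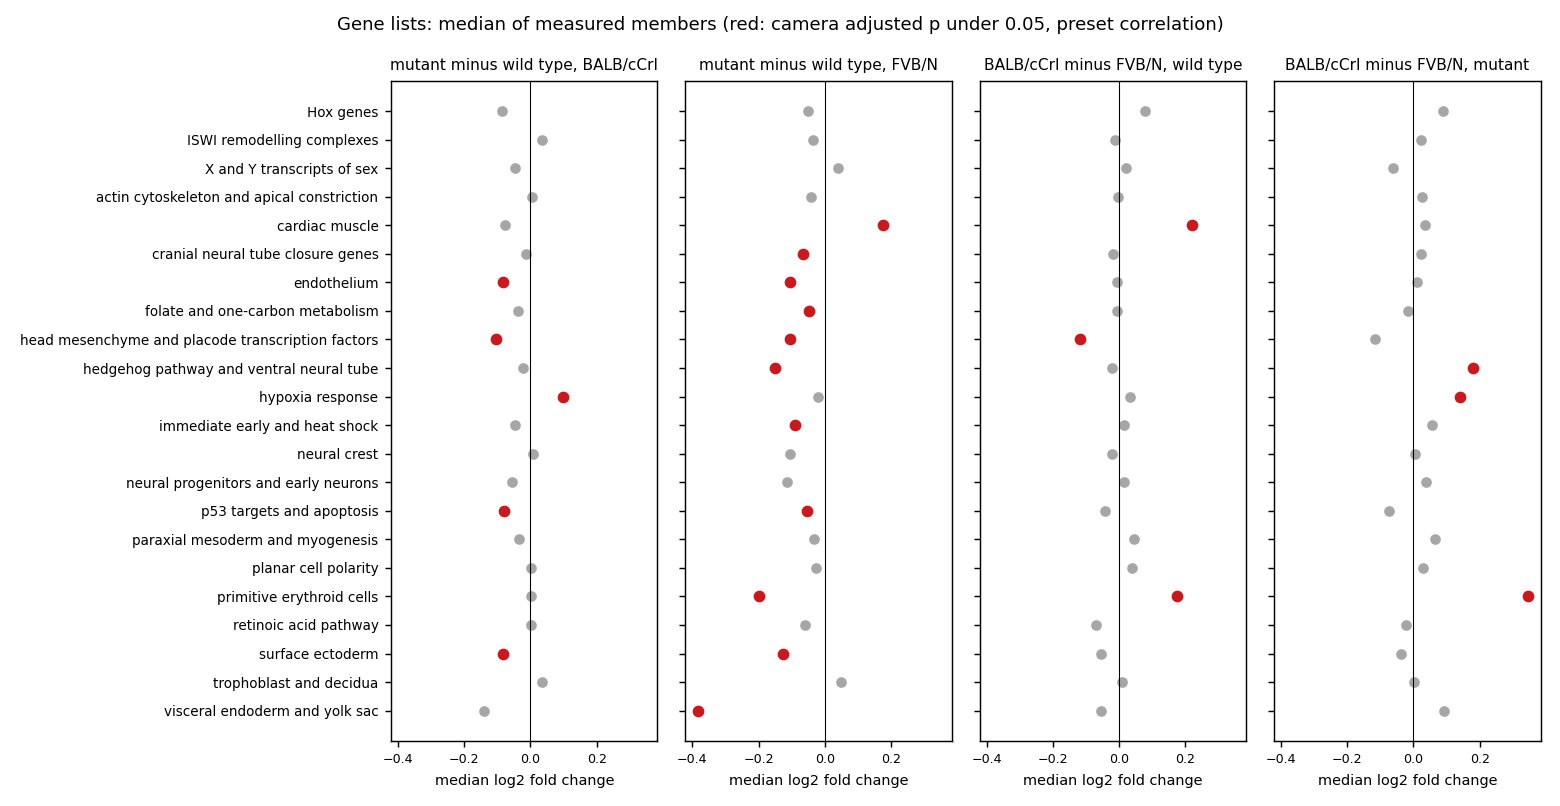
Median log2 fold change of the measured members of each of the 22 lists in 4 contrasts, 1 point per list, in red where the camera adjusted p was under 0.05 at the preset correlation. Red points number 5 for BALB/cCrl and 11 for FVB/N mutants against wild types, and 3 for the strains in each genotype.

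Wild type embryos of the strains were compared to ask how the genetic backgrounds differ at this stage. Snx6, a sorting nexin, was at least 42.6-fold lower in BALB/cCrl by one probe set (n = 4 per group), and Ifi204, an interferon-inducible gene, was at least 26.2-fold lower. Arl2bp was 12.2-fold lower (log2 fold change -3.61, SE 0.069), and its other probe set gave -3.39. Higher in BALB/cCrl were Gm6958 (38.6-fold, from FVB/N values of 4.70 to 5.36), the RNA-binding protein gene Tia1 by one probe set (at least 27.3-fold), Mtrex, an RNA helicase gene (at least 22.8-fold), and Rbm45 (14.6-fold). The folds of Snx6, Ifi204, Tia1 and Mtrex are bounds, since in the dimmer strain each lay within the range of the Y-linked probe sets, at 4.43 to 4.78, 3.17 to 3.74, 4.32 to 4.71 and 4.07 to 4.14. Casp9, an initiator caspase gene of the closure list, was 1.90-fold higher (0.93, SE 0.078), and all 3 of its probe sets were higher by 0.75 or more. Many of the largest differences stood in 1 probe set of a gene, since the other probe sets of Snx6 gave -0.47, -0.32 and -0.24, those of Tia1 -0.27 to -0.01, and those of Mtrex -0.30 and 0.06. Ptch1, the hedgehog receptor, was 2.98-fold lower by one probe set, and its other probe sets gave 0.10 and 0.09.

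Limma called 3036 probe sets between the wild types, 1296 higher and 1740 lower in BALB/cCrl, and 939 of them at 1.5-fold or more. The adjusted p was 5.3e-17 for Snx6, 9.5e-15 for Ifi204, 1.5e-17 for Arl2bp, 6.6e-16 for Tia1 and 6.9e-08 for Casp9. In the gcRMA table of this pair 1527 passed. Genes of chromosome 4 were called more often than others (116 of 1087, odds ratio 1.66, Fisher's exact test, adjusted p = 5.1e-05), as were those of chromosome 12 (64 of 622, odds ratio 1.57, adjusted p = 0.016), while for chromosome 6 the odds ratio of 0.841 did not pass. Phgdh, an enzyme of serine synthesis, was 36.3-fold lower in BALB/cCrl by one probe set with an SE of 1.17 (log2), while its other probe sets gave -0.30, -0.16 and -0.12. In that probe set BALB/cCrl wild type 1 stood at 11.23, near the FVB/N mean of 12.10, and the other BALB/cCrl wild types stood at 5.60 or less.

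Of 19 cardiac muscle genes 15 lay higher in BALB/cCrl than in FVB/N wild types, with a median log2 fold change of 0.22 (camera adjusted p = 5.6e-04, and adjusted p = 0.99 with an estimated correlation). Of these 5 passed over all probe sets and 10 adjusted over the list alone. Examples were Myl7, an atrial myosin light chain (1.29-fold, adjusted p = 0.0086), and Tnnt2, cardiac troponin T (1.33-fold, adjusted p = 0.017). Tnnt2 lost its call without FVB/N wild type 4 (0.051), BALB/cCrl wild type 2 (0.053) or BALB/cCrl wild type 3 (0.062). The cardiac results in FVB/N mutants and in the interaction use the same FVB/N wild types, so they are not independent of this one. Of those wild types, 3 and 4 lay lowest in Myl7 (12.74 and 12.58 against 13.03 and 13.00) and Tnnt2 (10.4 and 10.0 against 10.6 in both others). Primitive erythroid genes lay higher in 13 of 16 cases (median 0.18, adjusted p = 0.048, and adjusted p = 0.99 with an estimated correlation) with 0 past the test in limma over all probe sets or adjusted over the list alone. Head mesenchyme and placode factors lay lower in 15 of 23 cases (median -0.12, adjusted p = 0.050, just under the threshold), with 4 lower over all probe sets and 6 adjusted over the list alone, among them Prrx1 (1.45-fold lower, adjusted p = 0.0049). The list had an adjusted p of 0.99 with an estimated correlation. The number of called lists was 1 without FVB/N wild type 1, FVB/N wild type 2 or BALB/cCrl wild type 2. The erythroid list lost its call without these (0.60, 0.22 and 0.13) and without BALB/cCrl wild type 3 (0.23), and the head mesenchyme list without these (0.090, 0.14 and 0.13) and without FVB/N wild type 3 (0.086) or BALB/cCrl wild type 1 (0.098). Without BALB/cCrl wild type 1 and mutant 4 both lost their calls (0.0529 and 0.105), and so they did with the mean of a gene's probe sets (0.0614 each). The head mesenchyme list also lost its call after quantile normalisation (0.106) or median centring (0.0611). Among the 19 lists not called, neural crest genes included 4 that were lower over all probe sets, among them Cdh6 (3.17-fold by one probe set, -0.36 by the other), and closure genes 3 higher and 2 lower, with a median of -0.02 and a mean of 0.01.

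Mutant embryos of the strains were compared with the same question. Of 23 hypoxia genes 22 lay higher in BALB/cCrl than in FVB/N mutants, with a median log2 fold change of 0.14 (camera adjusted p = 1e-06, and adjusted p = 0.54 with an estimated correlation). Of these 7 passed over all probe sets and 12 adjusted over the list alone, among them Ndrg1 (2.22-fold, SE 0.131), which had 0.39 to 0.70 by its other probe sets, Bnip3, a mitophagy receptor (1.38-fold), and Pdk1, a kinase of pyruvate dehydrogenase (1.67-fold). Primitive erythroid genes lay higher in 15 of 16 cases (median 0.35, adjusted p = 2.4e-05, and 0.87 as the adjusted p with an estimated correlation), 6 of them over all probe sets and 8 adjusted over the list alone. Alas2, the first enzyme of erythroid heme synthesis, was 1.76-fold higher and Hba-x, an embryonic globin, 1.41-fold. Hedgehog genes lay higher in 15 of 19 cases (median 0.18, adjusted p = 0.0029, and 0.87 as the adjusted p with an estimated correlation), with 4 higher over all probe sets and 4 adjusted over the list alone, such as Gas1, a hedgehog co-receptor (1.55-fold), and Foxa2 (1.38-fold).

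Among ISWI remodelling genes, Bptf, a subunit of the NURF complex, was 1.45-fold higher in BALB/cCrl mutants than in FVB/N mutants (adjusted p = 3.2e-04) and Baz2a, a partner of the ISWI ATPase in the nucleolus, was 1.44-fold higher (adjusted p = 2.0e-04). Baz2b was also called and higher in BALB/cCrl mutants. Baz1a was called in the other direction, at 9.1 to 9.3 (log2) in BALB/cCrl mutants against 9.4 to 9.5 in FVB/N mutants. The calls of Baz1a and Baz2b were each lost without any 1 of 2 arrays. By the representing probe sets 2 of 13 members were higher and 0 lower, and the list as a whole was not called (adjusted p = 0.18). Of planar cell polarity genes Vangl2 was 1.31-fold higher (adjusted p = 0.0042) and Daam1 lower by a log2 fold change of -0.32 (adjusted p = 0.0022), in a list with 2 higher and 2 lower of 25 (adjusted p = 0.31). Cdk5rap1 was at least 12.4-fold higher and Tia1 at least 27.9-fold, with FVB/N mutants at the level of the Y-linked probe sets in both.

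Limma called 4861 probe sets between the mutants, 2201 higher and 2660 lower in BALB/cCrl (45.3% higher). At 1.5-fold or more 1136 remained, and there most were higher (660 higher and 476 lower, 58.1% higher). The adjusted p was 4.3e-06 for Ndrg1, 0.0017 for Bnip3, 0.0094 for Pdk1, 5.6e-04 for Gas1, 0.0032 for Foxa2 and 2.9e-15 for Cdk5rap1. The calls of Alas2 (adjusted p = 0.020) and Hba-x (0.030) were lost without FVB/N mutant 3 (0.071 and 0.10) or BALB/cCrl mutant 3 (0.068 and 0.090). That of Alas2 was also lost without BALB/cCrl mutant 4 (0.051), and that of Hba-x without FVB/N mutant 2 (0.072) or BALB/cCrl mutant 2 (0.066). The hedgehog list lost its call without FVB/N mutant 4 (0.064) or without FVB/N mutants 3 and 4 (0.0601). The number of called lists was 5 without FVB/N mutant 1 and 5 without BALB/cCrl mutant 1. On chromosome 6 fewer genes were called than elsewhere (80 of 992, odds ratio 0.664, Fisher's exact test, adjusted p = 0.0035), and on chromosomes 4 (odds ratio 1.42) and 12 (16.1% against 11.3% elsewhere) more.

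Strain differences overlapped widely between the genotypes. In the same direction 2042 probe sets were called in both, 879 higher in BALB/cCrl against an expected 63.3 and 1163 lower against an expected 103, and 6 were called in opposite directions. At 1.5-fold or more 707 were shared.

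A pair of BALB/cCrl arrays, wild type 1 and mutant 4, differed from the other 6 in the same way. In both, 34 probe sets lay at least 2-fold to one side of the median of the other 6 arrays, 33 of them higher, although not each lay outside the range of the 6. Gzmd, a granzyme of natural killer cells, stood at 7.24 and 8.14 (log2) in these arrays and at 2.93 to 3.36 in the other 14 arrays. Srgn, the proteoglycan of secretory granules, stood at 8.86 and 10.29 against 5.15 to 6.13 in those 14. H2-D1, a class I histocompatibility gene, stood at 9.23 and 8.97 by one probe set against 6.14 to 6.76 in the other 6 BALB/cCrl arrays and 9.35 to 9.92 in FVB/N. Phgdh stood at 11.23 and 11.29 against 5.60 or less in those 6 and 12.05 to 12.28 in FVB/N. By one probe set Tubb5, a tubulin gene, stood lower, at 10.90 and 11.06 against 12.38 to 12.64 in those 6 and 9.50 to 10.23 in FVB/N. Between wild types of the strains that probe set differed by 2.38 (log2) and another of Tubb5 by 0.05. The genes named for this pair were chosen after their values were seen.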

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

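The tests of the first 3 patterns, on chromosome 6, on single probe sets and on the pair of BALB/cCrl arrays, were chosen only after the results had been seen, while the counts over other splits of the arrays had been planned.

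In FVB/N, genes near Cecr2 on chromosome 6 were called more often than other genes. Beyond 30 Mb of Cecr2 the rate of calls was 0.972 times that of other chromosomes (2 of 575 genes, 95% limits 0.115 to 3.66), against 6.01%, 6.41% and 7.62% of genes at 0 to 10, 10 to 20 and 20 to 30 Mb, a stretch that DNA of the allele's donor kept beside the allele may explain. Ldhb stood at 10.4 to 10.6 (log2) in FVB/N wild types, 8.8 to 9.2 in FVB/N mutants and 8.7 to 9.0 in BALB/cCrl. Clec1b stood at 6.9 to 7.3, 8.4 to 8.7 and 8.0 to 8.5. In H2aj, Klhl42, Fgfr1op2, Recql, Zfand4, Emp1 and 3110021A11Rik too, FVB/N mutants lay near both BALB/cCrl groups. In Ncapd2, Cdca3, Zfp9, Etnk1 and Kdm5a they did not. This comparison was made after the data had been seen. Action of the trap on its neighbours in both strains is argued against for the genes called in FVB/N, since 21.1% of those within 20 Mb (4 of 19, 95% limits 6.05 to 45.6) followed in BALB/cCrl by at least 50% of the size. For the genes called in BALB/cCrl, such as Ncapd2, Cdca3 and Zfp9, it stays open, since 75% (3 of 4, limits 19.4 to 99.4) followed in FVB/N. Sequence variants under single probe sets stay open too. For genes within 20 Mb called in FVB/N by any probe set, 32% of the other probe sets followed (8 of 25, limits 14.9 to 53.5). These 25 belong to 16 genes and have a mean level above the median of all probe sets, and each was set against its gene's largest change. Ldhb and Recql, beyond 20 Mb, were not among them.

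Large strain differences often stood in 1 probe set of a gene. For genes with a 2-fold difference between wild types, the other probe sets with a mean level above the median were examined. Of these 15.4% (42 of 272, 95% limits 11.4 to 20.3) followed by at least 50% of the size, which is what sequence variants under the probes could give. The reference was each gene's probe set with the largest change, which by itself favours a low share. The limits treat the 272 probe sets of 146 genes as independent. Unequal background or saturation in 1 strain stays open, since quantile normalisation, which ended 2.63% of the 342 calls at 2-fold, moved them by a median of 0.024 (log2), below their median SE of 0.13, and so decides nothing. A real difference in expression remains an untested biological explanation for the 35 genes with a probe set that followed, such as Arl2bp.

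BALB/cCrl wild type 1 and BALB/cCrl mutant 4 lay at least 2-fold from the median of the other 6 arrays of the strain in 34 probe sets, of which 10 stood at FVB-like levels and 24 did not. For the 24, RNA of uterine cells of the dam is a candidate explanation, since 8 uterine genes not looked at before their list was written lay above the median by 0.248 (wild type 1) and 0.341 (mutant 4) on average, against at most 0.10 in the other 14 arrays. One member carried much of this, Gzmb (0.83 and 1.51), of the granzyme family already seen, and without it the other 7 averaged 0.164 and 0.174 (at most 0.095 in the other 14), while 5 of the 8 lay above the median in both arrays. At most 1 member of the planned trophoblast and decidua list stood at least 2-fold above the median in any array. For the fall in 1 probe set of Tubb5 uterine RNA is argued against, since dilution would need it to make up much of the RNA. The median of the 33 neural genes deviated by 0.095 and -0.036 only. For the FVB-like probe sets that were higher this cannot decide, since their levels in uterine cells were not measured. One of these, Tdo2 (7.67 and 8.27), is itself on the added uterine list. Stretches of another strain's DNA in these embryos may explain the FVB-like probe sets, since 10 of 24 further probe sets with a strain difference on chromosomes 3 and 17 lay over 30% of the way to the FVB/N mean in both arrays, against at most 3 in the other 27 pairs of BALB/cCrl arrays. No biological explanation from the groups was tested, since the arrays come from different groups, and the embryos had been dissected away from their membranes. The embryo numbers of both arrays in the labels follow each other directly. Whether these embryos shared a dam or a litter was not given and was not tested.

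Other splits of the arrays were counted for each contrast. In BALB/cCrl 3 of 35 splits gave at least as many called probe sets as the real 9, so chance could not be excluded, and the highest of the others, 270 with mutants 1, 2 and 3 and wild type 3 on one side, was several times the real count and points to a structure of the samples. In FVB/N 1 of 35 did (268, highest other 0), between wild types 1 of 35 (3036, highest other 5) and between mutants 1 of 35 (4861, highest other 422). That 1 was the real split, and 1 of 35 is the smallest share these splits allow. Splits that mix the strains put strain differences into the spread, which by itself keeps their counts low. In FVB/N the real split also carried the cross and the colony, which no split here can separate. For the interaction 3 of 100 draws, the real one included, gave at least as many (34, highest other 50). For the mean effect 1 of 100 did, the real one (205, highest other 21). A random draw also breaks up a genotype effect that both strains share, so the draws cannot decide for the interaction count. For the counts other than those of BALB/cCrl and the interaction, chance was thus unlikely but not excluded. For the number of called lists chance could not be excluded in any contrast. At least as many lists came from 10 of 35 splits in BALB/cCrl (real 5, highest other 9), 7 of 35 in FVB/N (11, highest other 13), 22 of 35 between wild types (3, highest other 9), 27 of 35 between mutants (3, highest other 12), 33 of 100 for the interaction (7, highest other 12) and 27 of 100 for the mean effect (8, highest other 13).

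Single arrays stood apart from the other 3 of their group in 24 of 354 tests of named genes, where chance gives about 1 in 20 groups. BALB/cCrl wild type 1 did so in Csn3 (gap 0.954 of the range, 7.87 against 7.79), Alx1 (0.857), Ssbp2 (0.891) and Phgdh (0.962). BALB/cCrl mutant 4 did so in Phgdh (0.904), Ptch1 (0.937), Daam1 (0.920) and Pdk1 (0.862, at 5.27 against 6.15 to 6.29). BALB/cCrl wild type 3 stood apart in Ncapd2 (0.885, at 10.61) and Pof1b (0.874), wild type 4 in Airn (0.878), mutant 1 in Klhl42 (0.875) and Wnt5a (0.846), and mutant 3 in Nkx2-9 (0.902). FVB/N wild type 1 stood apart in H2aj (0.887, above the others at 5.82 to 5.89), wild type 2 in Cecr2 (0.856, at 8.51 against 8.14 to 8.19) and Hhip (0.877), and wild type 3 in Pof1b (0.860). FVB/N wild type 4 stood apart in Hdhd5 (0.853), Aldh1a3 (0.899) and Myl3 (0.941, at 8.89 against 9.27 to 9.29). FVB/N mutant 1 stood apart in Zfand4 (0.833), mutant 2 in Kdm5a (0.899) and mutant 4 in Pdxdc1 (0.882).

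The difference between mutants and wild types was itself unlike in the 2 strains, by the test of the interaction in limma, in 17 named genes. On the log2 scale it was higher in BALB/cCrl for Cdk5rap1 (at least 3.38), Ldhb (1.54), 3110021A11Rik (1.27), Etnk1 (1.22), Mecr (1.19), Ro60 (1.08), Zfand4 (1.06), 4932438A13Rik (1.05), Mia3 (1.03), Kdm5a (0.97) and Emp1 (0.88). It was lower for H2aj (-1.91), Clec1b (-1.66), Klhl42 (-1.25), Fgfr1op2 (-1.05), Recql (-0.98) and Psmb2 (-0.53). These differences need not be effects of the trap, since in FVB/N the genotype went with the cross and the colony. Several of these genes lie on chromosome 6, where donor DNA beside the allele may explain the calls. Many of these calls rested on single arrays. Etnk1, Mecr, Ro60, 4932438A13Rik, Mia3, Kdm5a, Emp1, H2aj and Fgfr1op2 had other probe sets, of which 0 were called. The call was lost without any 1 of 13 arrays for Emp1, 12 for Etnk1 and Ro60, 11 for Zfand4 and Kdm5a, 10 for Mecr, 9 for Klhl42, 8 for 4932438A13Rik, 6 for Psmb2 and 3 for Mia3, and by leaving out no single array for the other 7. The interaction passed in 7 lists at the preset correlation, with an adjusted p of 3.9e-06 for the hypoxia response, 1.7e-05 for the hedgehog pathway, 1.9e-05 for cardiac muscle, 0.026 each for primitive erythroid cells and ISWI remodelling complexes, 0.035 for the neural crest and 0.046 for cranial neural tube closure genes. Of these, 0 were called with an estimated correlation (adjusted p 0.272 to 0.814), and the closure list lost its call without any 1 of 9 arrays, the erythroid and neural crest lists without any 1 of 6 and the ISWI list without any 1 of 4.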

How the results depend on the processing

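The settings without BALB/cCrl wild type 1 and mutant 4, and without FVB/N mutants 3 and 4, were chosen only after the data had been seen, and the others had been planned. FVB/N mutants 3 and 4 lay farthest from the wild types on the second principal component, so losses of calls without them were likely beforehand. Over all settings, the calls of single named genes were kept 2725 times and lost 451 times, and 0 changed direction. Of the results followed over these settings, those of Thbs1, Etnk1, Ro60, Zfand4 and Kdm5a fell most often below the threshold. Cecr2 and Ncapd2 kept their calls in BALB/cCrl in every setting run. The interaction of Emp1 was followed only by leaving out arrays, and its call was lost without any 1 of 13. The number of the replicate does not pair the samples, since arrays with the same number in different groups correlated above 0.1 in 6 of 24 pairs (-0.145 to 0.169), and using it as a block moved the interaction count to 89 and ended the calls of 5 named genes and of the Hox list in the mean effect (adjusted p = 0.0517). Scaling moved the median of all probe sets by less than 0.1 (log2). Array background limits weak signals, and changes near it could go unseen. No value came from the authors' other table of all groups, whose values are identical, or from a gcRMA table for the mutant pair, which held no values of these arrays, and in the gcRMA table of the BALB/cCrl pair the odds ratio for chromosome 6 could not be given, since 0 genes elsewhere were called. Except where fewer samples or a stricter threshold show it, the cause was not tested.

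Without the intensity trend the FVB/N count was 162 and the interaction count 20. With array weights the counts were 50 in BALB/cCrl, 69 for the interaction and 436 for the mean effect. Quantile normalisation gave 169 in FVB/N (39.1% higher) and centring on the median 14 in BALB/cCrl. The gcRMA pair tables gave 3 in BALB/cCrl, 13 in FVB/N (53.8% higher, against 29.5%) and 1527 between wild types. At 1.5-fold or more 87 remained in FVB/N, 939 between wild types, 1136 between mutants (58.1% higher, against 45.3% of all called), 18 for the mean effect and 707 in the overlap of the strain differences. With an estimated correlation 0 lists were called in each of the 6 contrasts by camera. With the mean of a gene's probe sets 1 list was called between wild types. Without the pair of BALB/cCrl arrays the counts were 22 in BALB/cCrl (59.1% higher, against 22.2%), 17 for the interaction and 445 for the mean effect (65.6% higher, against 33.2%), with 1 list between wild types. Without FVB/N mutants 3 and 4 they were 42 in FVB/N, 15 for the interaction and 70 for the mean effect, with 4, 3 and 5 lists in these contrasts.

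Leaving out each array in turn gave 8 to 115 probe sets in BALB/cCrl (77.4% of the 115 higher), 55 to 287 in FVB/N, 2383 to 2580 between wild types, 3514 to 4840 between mutants, 14 to 1.4e+02 for the interaction and 98 to 759 for the mean effect (65.5% of the 759 higher). Lists called numbered 4 to 6 in BALB/cCrl, 8 to 14 in FVB/N, 1 to 3 between wild types, 2 to 5 between mutants, 3 to 10 for the interaction and 7 to 12 for the mean effect. The odds ratio for chromosome 6 ranged from 4.54 to 43.2 in BALB/cCrl, from 4.79 to 24.7 in FVB/N, from 8.68 to 121 for the interaction and from 3.45 to 7.90 for the mean effect. The log2 fold change of Cecr2 ranged from -2.66 to -2.18 and from -2.44 to -2.25 by its probe sets in BALB/cCrl, from -3.11 to -2.76 and from -2.05 to -1.92 in FVB/N, and from -2.81 to -2.57 and from -2.22 to -2.13 for the mean effect. The one result that reversed was the visceral endoderm and yolk sac list in FVB/N, without FVB/N mutant 3 (adjusted p = 0.593), and its adjusted p was as low as 1.3e-04 without mutant 4.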

Other observations

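Of the lists fixed beforehand, 7 were called in no contrast. The trophoblast and decidua list, markers of tissues around the embryo, had 0 of 17 members past the test in limma over all probe sets in any of the 6 contrasts, and a camera adjusted p of 0.51 in BALB/cCrl, 0.42 in FVB/N, 0.97 between wild types and 0.99 between mutants. Neural progenitor and early neuron genes lay lower in 24 of 33 cases in FVB/N mutants (median log2 fold change -0.11, adjusted p = 0.092), with 1 higher and 2 lower adjusted over the list alone, and in 23 of 33 in BALB/cCrl mutants (median -0.06, adjusted p = 0.51). Paraxial mesoderm genes lay lower in 14 of 23 cases in FVB/N mutants (median -0.03, mean -0.12, adjusted p = 0.064). In wild types Meox2, a homeobox factor of somites and limb muscle, was 2.19-fold lower in BALB/cCrl than in FVB/N (adjusted p = 0.0015), in a list with a median of 0.04 and a mean of -0.09 there (adjusted p = 0.97).

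Genes of the actin cytoskeleton and apical constriction, the machinery that bends the neural plate, lay lower in 21 of 31 cases in FVB/N mutants (median -0.04, adjusted p = 0.098) and in 14 of 31 in BALB/cCrl mutants (adjusted p = 0.77), with 0 past the test in limma over all probe sets in either. Between mutants of the strains 4 of them were higher and 2 lower in BALB/cCrl (adjusted p = 0.31). Planar cell polarity genes had 0 of 25 members past the test in either strain (adjusted p = 0.87 in BALB/cCrl and 0.22 in FVB/N). In the retinoic acid pathway 1 of 17 genes, Aldh1a3, was called in FVB/N and lower in mutants (adjusted p = 0.28 for the list). Its call was lost without any 1 of 7 arrays. In BALB/cCrl 4296 and in FVB/N 5456 of all probe sets had an unadjusted p under 0.05. Of the 6 sex transcripts measured 0 were called in either strain (adjusted p = 0.72 and 0.22), and the Y-linked genes Uty and Eif2s3y averaged 3.24 and 3.35 in BALB/cCrl wild types.

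The authors' own adjusted p-values in the gcRMA tables lay under 0.05 for 3 probe sets in BALB/cCrl, 16 in FVB/N (8 higher and 8 lower) and 1418 between wild types. Of these, 3, 12 and 1216 were called here. Their log2 fold changes of Cecr2 were -3.50 and -3.86 in BALB/cCrl and -3.74 and -3.67 in FVB/N. Those of Alx1 were -1.22 (the authors' adjusted p = 0.092) and -0.93 (0.27).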
